A study of Mus musculus with 24 samples.

How the data were processed

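Total RNA from bone marrow of female C57BL/6J mice aged 6 weeks was measured on Agilent two-colour mouse arrays. Each of the 24 arrays carried a sample labelled with Cy3 and a common reference labelled with Cy5, a pool of marrow from oil-treated wild-type (WT) mice, with no dye swap. Per the labels each sample was a pool of 9, and the labels do not say whether these were mice. The labels give 50 mg/kg as the dose of every treatment.

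The deposited files per array hold intensity values (mean spot and median local background signal of each channel) from Feature Extraction 9.1.3.1, or 10.7.3.1 for the 4 arrays of slide 9, with no normalization between arrays. They also hold processed signals, which are intensity values that Feature Extraction had background-subtracted and dye-normalized, and per the file headers a LogRatio column on the log10 scale. The deposited table of the whole series holds log2 values, which in the authors' processing are differences between groups of the mean log2(Cy3/Cy5) of normalized arrays, in 9 columns of comparisons with no values per sample. The submitters' processing notes name limma, whose version is not given in the sources used here.

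The per-array intensities were read into R 4.3.3 with the package data.table (version 1.17.8) and analysed with limma 3.58.1 and statmod 1.5.0. Local background was subtracted with normexp (offset 50), and log ratios M = log2(Cy3/Cy5) were normalized within each array by loess, with no scaling between arrays. Control features were left out. Probes were named with the mouse annotation of GRCm38.p6 by accession (26888 probes), by the name in the file (8429), by symbol (5025) or by synonym (832). The brightest probe of each gene was kept, and a gene was tested if its Cy3 signal was well above background, as Feature Extraction called it, on at least 3 arrays, in whatever groups. This left 24491 genes. For 13 of them the single double-null oil array had no value.

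One linear model with a mean for each of the 10 groups was fitted across all 24 arrays, and 12 comparisons were taken from it with limma's moderated statistic. P values were adjusted over all genes tested by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Errors given with ± are standard errors from this fit. The double-null oil group had 1 array, which was assumed to vary like the other groups. Deviations of log ratios from the mean of their group correlated at r from -0.25 to 0.33 across genes between arrays of 2 groups with the same replicate number, and no pairing was used. A block for replicate number was run as an alternative. The number of arrays limits the precision of every value.

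The mouse groups, comparisons, gene lists and the rule for naming genes were fixed before the data were examined. The rule named Cyp1a1 and Cyp1b1 in every comparison. It named the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between the groups, or among called genes for a difference of responses. In each list with at least 2 called members or a list call it named up to 4 members with the smallest adjusted p and any called member going the other way. It gave 333 genes in 623 pairs of gene and comparison, of which 3 genes are not reported here. For a gene with no array well above background in one group, a bound was computed from Cy3 signals, with each array of that group at no less than its lowest signal well above background, and is given as "at least" a fold where most arrays of the other group were well above background and none had a high floor. No change is given where 1 of 2 or 1 of 3 arrays of a group was so.

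The 29 gene lists covered responses (AhR battery, p53 and NRF2 targets, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, immediate early genes, integrated stress response, glucocorticoid-responsive genes, circadian clock, heme and iron, S phase, G2 and M phase, ribosomal proteins) and cell types of marrow and tissue that can be carried over with it. They were tested in every comparison (348 tests, adjusted together) with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with all other genes, and fry tests whether its members move one way on balance. Counts of called members are given over all genes tested and adjusted over the list alone. With an estimated correlation no list was called in any comparison, and fry called 10.

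The alternatives fixed beforehand were no background subtraction, Feature Extraction's processed signals, no filter, a filter on 12 arrays, the mean of probes, Cy3 alone scaled to each array's 75th percentile, Aquantile scaling, slide as a random block (consensus correlation 0.821) or fixed term, replicate block, Feature Extraction version as a random block (consensus correlation 0.250) or fixed term, a trended robust prior, only the groups compared, and leaving out each replicate in turn. Added after seeing the data were the fits without WT oil replicate 1 where the comparison does not use the oil arrays, and in every comparison those with slide as a random block as well (consensus correlation 0.567) or with processed signals as well, and also array weights, log ratios scaled to one spread, and fits on the arrays of one slide. Fits from the authors' values per sample could not be run, since the deposited table holds comparisons only, and scan day was the same as slide.

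Simulated data with 200 changed genes tested the fits. At a log2 change of 1 they recovered 18% to 69% over the comparisons, and 63% to 96% at 2. Of 348 list tests the 3 shifted were called and no others. Slide and gene correlations were not tested.

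Comparisons that share the WT oil arrays move together for that reason alone, so overlaps between them are given beside the number for independent comparisons and the covariance in 20 simulations with shared controls and no change.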

Results

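Gene expression was measured in bone marrow of WT mice and of mice without Cyp1b1, Cyp1a1 or both genes (double-null), after an intraperitoneal injection of olive oil or of a ligand of the aryl hydrocarbon receptor (AhR). BP (benzo[a]pyrene) and DMBA (dimethylbenz[a]anthracene) are polycyclic aromatic hydrocarbons that CYP1A1 and CYP1B1 oxidise, and TCDD (tetrachlorodibenzo-p-dioxin) is a chlorinated dioxin that resists metabolism. The WT groups held 3 arrays after oil, 2 at 6 h after BP, 3 at 12 h after DMBA and 3 at 12 h after TCDD. The Cyp1b1-null groups held 2 arrays after oil and 2 at 12 h after DMBA, the Cyp1a1-null groups 3 after oil and 3 at 12 h after BP, and the double-null groups 1 after oil and 2 at 12 h after BP.

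Cy3 signals were well above background for 38.3% (WT TCDD replicate 1) to 84.8% (WT oil replicate 2) of the probes of an array, and Cy5 signals for 45.8% to 87.7%. The 5th percentile of log2 Cy3 was 7.85 and 9.14 in WT TCDD replicates 1 and 2 and 8.18 and 8.75 in the Cyp1b1-null DMBA arrays, against 5.87 to 7.12 in the other arrays. A high floor draws the log ratio of a dim gene towards 0. For such genes values from Feature Extraction's processed signals, without WT oil replicate 1, are given too. WT oil replicate 1 stood apart. The standard deviation of its log ratios was 1.10, against 0.18 to 0.58 elsewhere. Its Cy5 had a median Spearman correlation of 0.751 with the other arrays' common reference, against 0.892 (WT oil replicate 2) or more elsewhere. Its Cy3 was at 0.926 (lowest other 0.922), but a list of liver genes lay at a median percentile of 96.1 in it and at 34.3 at most elsewhere. All comparisons were therefore also fitted without this array, with those values in brackets after most log2 changes and list medians against WT oil. That fit leaves WT oil replicates 2 and 3, whose log ratios had an r of 0.129. Naming genes again from this fit, and combining it with other settings, were chosen after seeing the data.

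The arrays were on 10 slides. Across genes, which are not independent replicates, log ratios of arrays on one slide correlated at a mean r of 0.717 within groups (12 pairs) and 0.637 between groups (11 pairs), against 0.196 (7 pairs) and 0.209 (246 pairs) on different slides. The lowest correlation of any pair was -0.345. WT BP, WT TCDD, Cyp1b1-null DMBA and double-null arrays filled a slide each, so slide is not told from group, or for double-null from genotype. Slide as a random block used slides shared by groups. A log ratio is given as log2(Cy3/Cy5), and a log2 change as mean ± standard error. Each gene named as risen or fallen between groups had every array of one group beyond every array of the other. Chance alone gives that to 10% of genes with 3 against 3 arrays, 20% with 2 against 3, 33.3% with 2 against 2, 50% with 1 against 3 and 66.7% with 1 against 2. For a list of genes, counts are of members called among all genes, and counts adjusted over the list alone are given beside them.

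**Figure D1:**
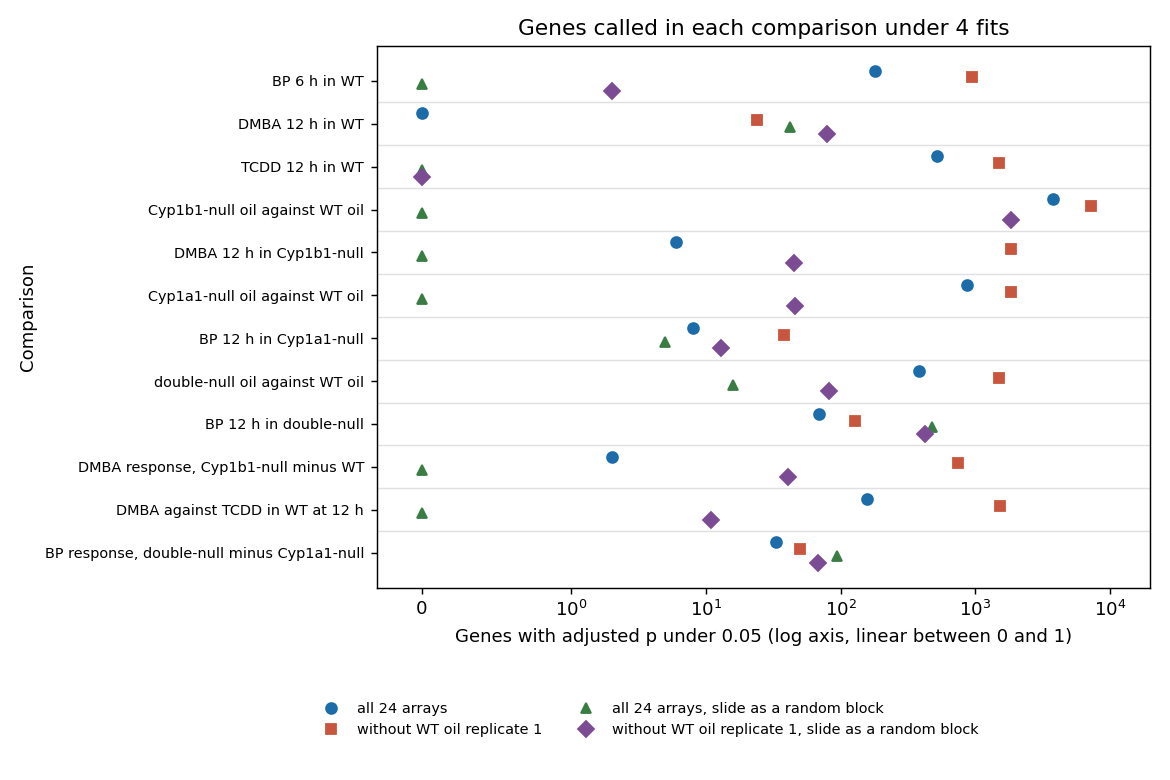
Genes called in each of the 12 comparisons (adjusted p under 0.05; symmetric log axis) with all arrays, without WT oil replicate 1, with slide as a random block, and with both changes. The count for DMBA in WT is 0 with all arrays and 24 without WT oil replicate 1, and that for Cyp1b1-null oil is 3764 and 7255.

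The first comparison asked what BP had changed in WT marrow by 6 h. Ahrr, Cxcl10, Il1a and Irf7 rose, and Ppbp and Retnla fell. Cyp1a1 (chromosome 9), the classic AhR target, was well above background on both BP arrays and, of the 3 oil arrays, on replicate 1 alone, so no change is given. Cyp1b1 (chromosome 17) stood at 0.41 ± 0.22, adjusted p = 0.362 (0.31). The AhR repressor Ahrr 1.87 ± 0.35 (2.19) and the quinone reductase Nqo1 0.75 ± 0.15 (0.78), also AhR targets, rose, as did the macrophage glycoprotein Gpnmb 1.33 ± 0.26 (1.47). The chemokine Cxcl10 2.65 ± 0.32 (2.56) and the cytokine Il1a 2.44 ± 0.26 (2.26) rose with them. The transcription factors Hic1 2.46 ± 0.32 (2.31) and Maff 1.34 ± 0.27 (1.51) rose too. Among interferon-stimulated genes Irf7 1.23 ± 0.19 (1.06) and Gbp2 1.25 ± 0.25 (0.90) rose. Cxcl3 and Mx1 were called too, but were well above background on 1 of 3 oil arrays, so no change is given. The largest falls were the platelet chemokine Ppbp -2.07 ± 0.44 (-1.96) and the macrophage product Retnla -1.97 ± 0.36 (-1.63). Eif1ax -1.41 ± 0.31 (-0.96), Psph -1.33 ± 0.29 (-1.06), Hnrnpc -1.29 ± 0.25 (-1.04), Srsf1 -1.26 ± 0.26 (-0.83) and Ska2 -1.23 ± 0.24 (-0.90) fell with them. Their adjusted p lay between 0.00106 and 0.0425. The fit without WT oil replicate 1 added rises of Cxcl2 3.83 ± 0.55, Nfkbiz 3.12 ± 0.34, Spint1 2.65 ± 0.39, Ptgs2 2.58 ± 0.56, Egr2 2.55 ± 0.30, Tnf 2.44 ± 0.21, Tiparp 1.53 ± 0.17 and Dusp1 2.17 ± 0.42 (adjusted p from 4.05e-05 to 0.019). It also added falls of Treml1 -1.40 ± 0.35, Myl9 -1.76 ± 0.32 and Cavin2 -1.71 ± 0.34 (adjusted p from 0.00752 to 0.0329).

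Of the 17 measured genes of the AhR battery 3 rose, 6 adjusted over the list alone (median 0.79 (0.37); camera adjusted p = 1.90e-05, 0.737 with an estimated correlation). Of 28 interferon-stimulated genes 5 rose, 15 adjusted over the list alone (camera adjusted p = 4.59e-09, 0.737 with an estimated correlation). The rotation test fry called both lists (adjusted p = 0.0177 for each). Of 21 inflammatory cytokines and NF-kB targets 1 rose, 9 adjusted over the list alone (camera adjusted p = 1.38e-04, 0.944 with an estimated correlation). In the fit without WT oil replicate 1 the counts were 16 and 19 (camera adjusted p = 8.51e-23, 0.114 with an estimated correlation). Immediate early genes had 9 of 17 members higher without that array, 12 adjusted over the list alone (camera adjusted p = 3.22e-11, 0.2 with an estimated correlation). Of 22 megakaryocyte and platelet genes 1 fell, 11 adjusted over the list alone (camera adjusted p = 8.62e-07, 0.944 with an estimated correlation), and 4 fell without that array. Cy3 alone gave this list no direction (camera adjusted p = 0.778). In all 180 genes were called, 47 higher and 133 lower, against 948 (368 and 580) without WT oil replicate 1, with all 180 among them. Leaving out WT oil replicate 2 or 3 gave 1049 or 1516 genes, and leaving out BP replicate 1 or 2 gave 6 or 13. limma with slide as a random block called 0 genes (380 at an unadjusted p under 0.05), and 2 without WT oil replicate 1.

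The second comparison asked what DMBA had changed in WT marrow by 12 h. Spint1 and the p53 target Phlda3 rose without WT oil replicate 1, and the number of called genes depended on the fit. With all 24 arrays limma called 0 genes (3025 at an unadjusted p under 0.05; lowest adjusted p = 0.0606), and without WT oil replicate 1 it called 24, 22 higher and 2 lower. For Cyp1a1, well above background on all 3 DMBA arrays and 1 of 3 oil arrays, no change is given. Cyp1b1 stood at 0.28 ± 0.20, adjusted p = 0.492 (0.17). Also without that array, rises were seen for the protease inhibitor gene Spint1 2.19 ± 0.36, the p53 target Phlda3 1.19 ± 0.20, the sulfatase Sulf2 0.88 ± 0.14, the GTPase gene Arl4c 0.86 ± 0.13 and the scavenger receptor Msr1 0.76 ± 0.14. The 2 falls were Aldh1a7 -1.01 ± 0.18 and Armc9 -0.78 ± 0.14 (adjusted p = 0.047 or less for each). The cell cycle brake Ccng1, another p53 target, stood at 0.92 ± 0.16, adjusted p = 0.151 (0.82). It rose by 0.86 ± 0.15, adjusted p = 0.0351 with slide as a block and without WT oil replicate 1.

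The AhR battery had 0 of 17 members called, 2 adjusted over the list alone (median 0.41 (0.18); camera adjusted p = 8.63e-05, 0.944 with an estimated correlation; fry adjusted p = 0.0358). Of 30 p53 targets 0 were called, 3 adjusted over the list alone (camera adjusted p = 0.163). These counts were, without WT oil replicate 1, 1 and 3 (camera adjusted p = 0.00164, 0.2 with an estimated correlation). Erythroid genes had a median of -1.24 (-0.27) with 0 of 29 called and 7 lower adjusted over the list alone (camera adjusted p = 1.37e-13, 0.944 with an estimated correlation). The latter count was 2 without WT oil replicate 1 (camera adjusted p = 4.84e-06, 0.649 with an estimated correlation), and Cy3 alone put the list higher (0.00798). The carbonic anhydrase gene Car1 (-1.32 ± 0.28; -0.92), Klf1 (-1.07 ± 0.32; -0.50) and Gata1 (-0.86 ± 0.24; -0.44) were the members with the smallest adjusted p, 0.298 at the lowest. The count was 842 without WT oil replicate 2 and 77 without replicate 3. WT oil replicate 2 and DMBA replicates 1 and 2 shared a slide. With slide as a random block 42 genes were called (39 higher, 3 lower), and 79 also without WT oil replicate 1. A fixed slide term gave 223, and that slide alone 7247, where the lone oil array was assumed to vary like the rest.

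The third comparison asked what TCDD had changed in WT marrow by 12 h. Osgin1, Chac1 and Hspa1b rose and Spp1 fell, as in Cyp1a1-null oil. Ccng1 and platelet and pan-B list members fell. No change is given for Cyp1a1, well above background on 2 of 3 TCDD arrays and 1 of 3 oil arrays, or Cyp1b1, on no TCDD array and 2 of 3 oil arrays. With processed signals, whose background method differs here, Spint1 and Ahrr stood higher, by 2.61 ± 0.34, adjusted p = 0.00207 and 2.34 ± 0.59, adjusted p = 0.0248. The normexp fit gave 0.12 ± 0.50, adjusted p = 0.915 (0.87) and -0.30 ± 0.31, adjusted p = 0.605 (0.02). The largest rises were the liver-enriched factor Creb3l3 2.16 ± 0.51 (1.48), Enho 1.92 ± 0.47 (1.08), the NRF2 target Osgin1 1.81 ± 0.38 (1.13), and the heat shock gene Hspa1b 1.62 ± 0.35 (1.71). Next came pyruvate carboxylase Pcx 1.45 ± 0.36 (0.82), the integrated stress response gene Chac1 1.42 ± 0.24 (1.47), the linker histone H1f0 1.42 ± 0.24 (1.07) and Anxa4 1.30 ± 0.33 (1.05). The largest falls included Fam111a -2.18 ± 0.52 (-1.24), Nrros -2.10 ± 0.52 (-1.13), Ppbp -2.04 ± 0.40 (-1.93), Apaf1 -1.99 ± 0.41 (-1.41), Scd2 -1.95 ± 0.48 (-1.06), Cdc42se1 -1.95 ± 0.34 (-1.38) and Klhl6 -1.94 ± 0.45 (-1.13). Osteopontin (gene Spp1 -1.32 ± 0.15 (-1.31)), Cd38 -1.82 ± 0.29 (-1.74), Ccng1 -0.81 ± 0.16 (-0.91) and the chromatin remodeler Hells -1.56 ± 0.36 (-0.93) fell. The B-lineage genes Ralgps2 -0.73 ± 0.17 (-0.64) and Pou2f2 -0.46 ± 0.11 (-0.41), the platelet gene Treml1 -1.29 ± 0.29 (-1.27) and the macrophage gene Cd68 -0.54 ± 0.12 (-0.39) fell too, and the complement gene C1qb 1.01 ± 0.22 (0.67) rose. Adjusted p of these genes ran from 0.00109 (Spp1) to 0.0496. The fit without WT oil replicate 1 added rises of Hspa1a 3.02 ± 0.44, Nr4a1 1.69 ± 0.24, Hbb-bt 1.64 ± 0.25 and Rpl32 1.02 ± 0.14 (adjusted p from 0.00276 to 0.00424) and a fall of the eosinophil gene Epx (-1.36 ± 0.26, adjusted p = 0.0103). Anxa4 and Pou2f2 lost their calls there (adjusted p = 0.0661 and 0.0552).

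Of 22 megakaryocyte and platelet genes 2 fell, 7 adjusted over the list alone (camera adjusted p = 1.54e-05, 0.944 with an estimated correlation), and 3 fell without WT oil replicate 1 (camera adjusted p = 6.76e-04, 0.649 with an estimated correlation). Of 16 pan-B genes 2 fell, 9 adjusted over the list alone (median -0.95; camera adjusted p = 1.95e-06, 0.944 with an estimated correlation), and 3 without that array (median -0.38). Ribosomal protein genes had a median of -0.17 (0.35) and no member called. Without that array 14 rose and 1 fell, 15 and 4 adjusted over the list alone (camera adjusted p = 4.52e-05, 0.431 with an estimated correlation). In all 519 genes were called, 71 higher and 448 lower, against 1509 (549 and 960) without WT oil replicate 1, which shared 429. Leaving out WT oil replicate 2 or 3 gave 4342 or 2073 genes, and leaving out TCDD replicate 1, 2 or 3 gave 83, 177 or 14. A random slide block left 0 genes called by limma (489 at an unadjusted p under 0.05), and 0 also without WT oil replicate 1 (2755).

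Changes after BP and TCDD shared WT oil arrays. Without WT oil replicate 1 they had 123 higher and 161 lower genes in common (8.25 and 22.7 if independent). TCDD in WT and Cyp1b1-null oil shared 420 and 571 (94.8 and 119). Simulations with shared controls and no change called 0.05 shared genes on average. The covariance of log2 changes was 0.0605 and 0.168. Over all 15 pairs against WT oil it ran from 0.0307 (DMBA and Cyp1a1-null oil) to 0.176 (Cyp1b1-null and double-null oil), simulated 0.0585 to 0.0589. Slides were not simulated, and a common or TCDD response was not told from shared arrays here.

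DMBA and TCDD were compared directly in WT marrow at the same time of 12 h, without the oil arrays. DMBA left Ccng1, Phlda3 and Spp1 higher, and TCDD left Hspa1a and Hspa1b higher. DMBA is a hydrocarbon with methyl groups that is oxidised to DNA-binding products, and TCDD carries chlorine atoms. Of p53 targets, Ccng1 was higher after DMBA by 1.73 ± 0.16, adjusted p = 8.67e-05 (1.05e-08 to 0.702 over the alternatives) and Phlda3 by 1.60 ± 0.20, adjusted p = 0.00224, in 3 of 3 against 3 of 3 arrays. Osteopontin (Spp1) was higher after DMBA by 2.10 ± 0.15, adjusted p = 3.97e-06. The lysophospholipid receptor Lpar6 1.62 ± 0.22, Cd38 1.51 ± 0.29, the single-strand DNA binding gene Nabp1 1.26 ± 0.23 and the chemokine Ccl9 1.24 ± 0.19 were also higher after DMBA. Of stress genes, higher after TCDD were Hspa1a -2.93 ± 0.64, Hspa1b -1.83 ± 0.35 and Chac1 -1.26 ± 0.24. So were the erythroid gene Car1 -1.55 ± 0.28, the linker histone H1f0 -1.17 ± 0.24 and Arhgef25 -1.37 ± 0.28, Rusf1 -1.12 ± 0.21 and Ppm1l -1.12 ± 0.19. Adjusted p of those given without one ran from 0.00295 to 0.0487. For AhR targets fits disagreed. Cyp1a1 was higher after DMBA by 1.25 ± 0.26, adjusted p = 0.0413 (4.27e-05 to 1 over the alternatives). With processed signals its difference of 2.81 ± 1.21, adjusted p = 0.141 did not pass. Ahrr differed by 1.15 ± 0.31, adjusted p = 0.126 and Spint1 by 1.32 ± 0.50, adjusted p = 0.357. With processed signals they differed by 0.12 ± 0.53 and -0.30 ± 0.30 (adjusted p = 0.91 and 0.556). Cyp1b1 was well above background on all 3 DMBA arrays and no TCDD array, so no difference is given.

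Of 30 p53 targets 2 were higher after DMBA and 0 after TCDD, 5 higher adjusted over the list alone (camera adjusted p = 9.59e-05, 0.0915 with an estimated correlation; fry adjusted p = 0.00355). As many as 10 were higher without WT oil replicate 1. Monocyte and macrophage genes had 1 of 29 higher, 2 over the list alone with 1 lower (camera adjusted p = 0.0178, 0.737 with an estimated correlation). Of the megakaryocyte and platelet genes 0 were called and 5 were higher adjusted over the list alone (camera adjusted p = 5.52e-05, 0.944 with an estimated correlation). Erythroid genes had 1 of 29 lower after DMBA, and 1 adjusted over the list alone (camera adjusted p = 3.57e-05, 0.944 with an estimated correlation). Without WT oil replicate 1, which enters only through the variance, the count was 13, and 18 adjusted over the list alone. In all 158 genes were called, 128 higher and 30 lower after DMBA, against 1531 (1083 and 448) without WT oil replicate 1. Leaving out DMBA replicate 1, 2 or 3 gave 28, 41 or 21 genes, and leaving out TCDD replicate 1, 2 or 3 gave 33, 87 or 24. The random slide block left limma with 0 genes (354 at an unadjusted p under 0.05). It left 11 without WT oil replicate 1, among them Ccng1 and Spp1 (adjusted p = 0.00335 for each).

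**Figure D2:**
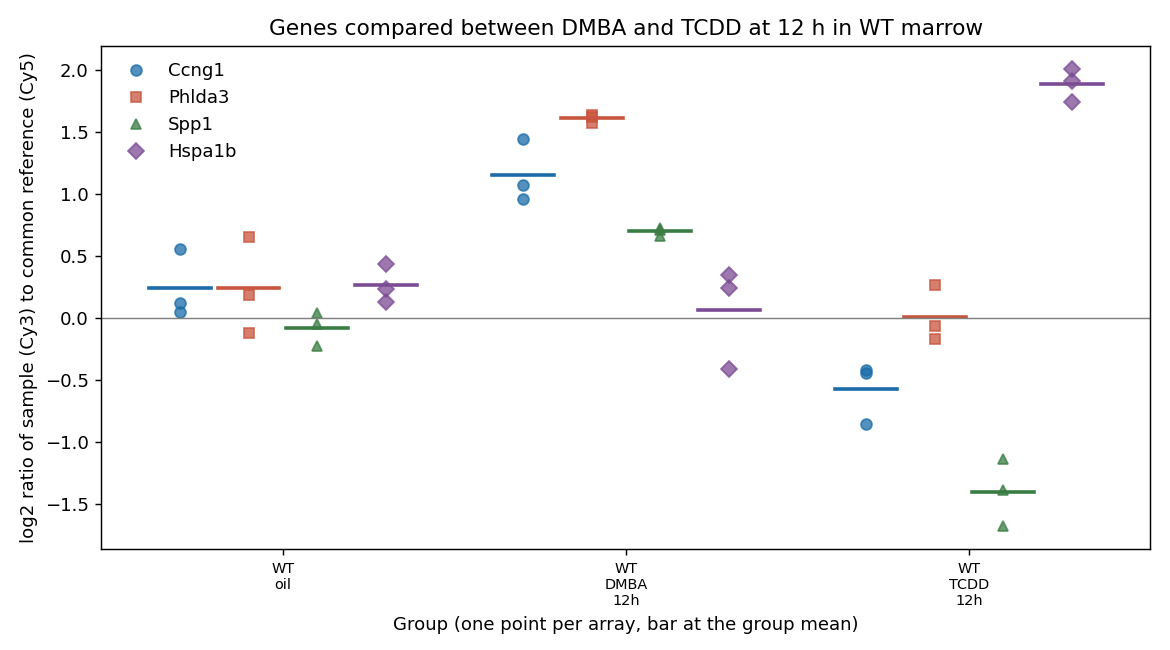
Log ratio, log2(Cy3/Cy5), of Ccng1, Phlda3, Spp1 and Hspa1b in each WT oil, DMBA 12 h and TCDD 12 h array (points) with the group mean (bar). Ccng1, Phlda3 and Spp1 lie higher in all 3 DMBA arrays than in all 3 TCDD arrays (log2 differences of 1.73, 1.60 and 2.10), and Hspa1b lies lower (-1.83).

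Cyp1b1-null and WT marrow were compared after oil, which asks what loss of Cyp1b1 alone changed. Ugt2b34 and Creb3l3 were among the largest rises, and Fcrla, Rag1 and Cd79b among the largest falls. Cyp1a1 was well above background on neither Cyp1b1-null array and 1 of 3 WT oil arrays, so no change is given, and the Cyp1b1 probe stood at 0.64 ± 0.22, adjusted p = 0.0567 (0.53). The probe gave no sign of the deletion, and its place relative to the deleted part is not given in the sources used here. The largest rises with all arrays were the glucuronosyltransferase Ugt2b34 4.46 ± 0.80 (3.80), the clotting and fibrinolysis genes Proz 4.33 ± 0.94 (2.94), Cpb2 4.06 ± 0.68 (3.00) and Hrg 3.98 ± 0.80 (3.05) and the fatty acid hydroxylase Cyp4a10 4.00 ± 0.81 (2.83). Next came Creb3l3 3.91 ± 0.57 (3.23), glucose-6-phosphatase G6pc 3.45 ± 0.66 (2.58) and the steroid hydroxylase Cyp3a41a 3.33 ± 1.06 (1.52). All 8 were smaller without WT oil replicate 1, in whose Cy5 channel, the divisor of its log ratios, liver genes lay at a median percentile of 99.8, against 32.6 at most elsewhere. Log ratios of Ugt2b34 were 3.11 and 3.03 here and 3.68 and 3.22 on the 2 Cyp1a1-null BP arrays of the same slide, against 0.26 on the BP array of another slide. The largest falls included the B-cell genes Fcrla -3.74 ± 0.93 (-2.16), Cd79b -3.25 ± 0.96 (-1.66) and Fcmr -2.78 ± 0.76 (-1.52), the recombinase Rag1 -3.15 ± 0.76 (-1.99) and the lymphocyte receptor Gpr171 -2.62 ± 0.86 (-1.11). Ctse -2.60 ± 0.85 (-1.11) and Pafah1b3 -2.56 ± 0.65 (-1.57) fell, as did the X-inactivation RNA Xist, at log ratios of -0.15 and -3.97 in replicates 1 and 2, the latter not well above background. The B-lineage genes Ebf1 -1.68 ± 0.36 (-1.14), Blk -1.52 ± 0.30 (-1.22), Spib -2.40 ± 0.61 (-1.39) and Bach2 -2.37 ± 0.53 (-1.59) fell too. They were joined by the erythroid genes Klf1 -1.45 ± 0.36 (-0.88) and Trim10 -2.42 ± 0.58 (-1.45) and the replication genes Cdc45 -1.79 ± 0.40 (-1.11) and Mcm5 -2.07 ± 0.54 (-1.19). The macrophage genes C1qb 1.73 ± 0.24 (1.39) and Fcgr1 1.21 ± 0.19 (1.22) rose. Adjusted p of these ran from 0.00122 to 0.0496. Spint1 was lower than in WT oil with processed signals, at -2.10 ± 0.37, adjusted p = 0.00237, and the normexp fit gave -1.64 ± 0.55, adjusted p = 0.0546 (-0.89).

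Of 16 pan-B genes 9 fell, 11 adjusted over the list alone (camera adjusted p = 1.36e-06, 0.944 with an estimated correlation). Without WT oil replicate 1, 8 fell and Pax5, well above background on 1 of 3 WT oil arrays, was called higher (camera adjusted p = 4.86e-04, 0.67 with an estimated correlation). Of 18 common lymphoid and pro-B genes 8 fell and 1 rose (Igll1, 0.67 ± 0.18, adjusted p = 0.0238 (0.71)), with the same counts adjusted over the list alone (camera adjusted p = 2.02e-05, 0.944 with an estimated correlation). Mature B genes had 6 of 15 lower, 11 adjusted over the list alone (camera adjusted p = 5.52e-05, 0.944 with an estimated correlation). Of 29 erythroid genes 6 fell, 13 adjusted over the list alone (median -1.50 (-0.34); camera adjusted p = 5.76e-07, 0.944 with an estimated correlation). Leaving out that array, 3 rose and 11 fell. Monocyte and macrophage genes went both ways, 6 of 29 higher and 2 lower (camera adjusted p = 0.293, fry 0.0251), and 8 and 2 adjusted over the list alone. In all 3764 genes were called, 2088 higher and 1676 lower, against 7255 (4229 and 3026) without WT oil replicate 1, which shared 3486. Omitting WT oil replicate 2 gave 6071 genes, and leaving out Cyp1b1-null oil replicate 1 or 2 gave 273 or 206. These arrays shared a slide with Cyp1a1-null BP replicates 1 and 2. When slide was a random block limma called 0 genes (2532 at an unadjusted p under 0.05), and 1856 (930 higher, 926 lower) without WT oil replicate 1.

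**Figure D3:**
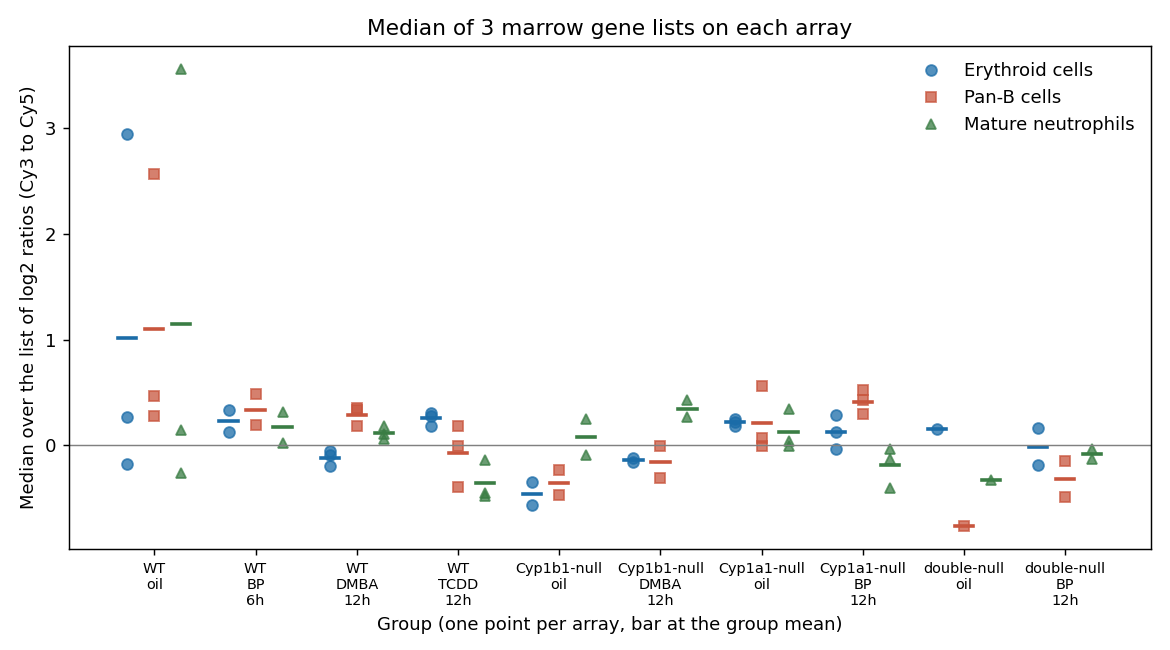
Median log ratio, log2(Cy3/Cy5), of the erythroid, pan-B and mature neutrophil lists in each array (points), by group. WT oil replicate 1 lies far above all other arrays, at 2.94, 2.57 and 3.56.

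DMBA was given to Cyp1b1-null mice to ask what effects remain. Spint1 and Dpep2 rose with processed signals and without WT oil replicate 1, and Kdelr2 and Cox6a1 fell with all arrays. Both high-floor DMBA arrays and neither oil array were well above background for Cyp1a1 (log ratios 0.23 and 0.04 against 0.02 and -0.01), so no change is given. Cyp1b1 stood at -0.70 ± 0.24, adjusted p = 0.189 (-0.86 to 0.42, lowest adjusted p 1.33e-04, over the alternatives). With processed signals Spint1 rose by 3.52 ± 0.37, adjusted p = 0.00157, the dipeptidase Dpep2 by 2.13 ± 0.35, adjusted p = 0.0091 and the AhR target Tiparp by 1.15 ± 0.31, adjusted p = 0.0376. For Ahrr and Gpnmb, called higher too, no change is given (1 of 2 oil arrays well above background). Without WT oil replicate 1, which enters only through the variance, processed signals called 1908 genes, and 2 with all arrays, where not all of these pass. The normexp fit gave 1.25 ± 0.61, 0.35 ± 0.28 and 0.64 ± 0.52 (adjusted p of 0.359 or more). With all arrays the called genes were 1 rise and 5 falls, among them Lrrc47 0.91 ± 0.14, the secretory pathway receptor Kdelr2 -1.92 ± 0.30, the cytochrome oxidase subunit Cox6a1 -1.73 ± 0.23 and the endosomal gene Wdfy1 -1.26 ± 0.20 (adjusted p from 0.0143 to 0.0476), beside 2 probes with no gene symbol. With scaled log ratios Wdfy1 turned to 3.19. The fit without WT oil replicate 1 added rises of the p53 targets Ccng1 0.77 ± 0.18 and Cdkn1a 0.98 ± 0.26, of the T-cell kinase Lck 1.06 ± 0.23 and the galectin Lgals3 1.34 ± 0.32. It added falls of the erythroid and iron genes Hbb-bt -1.93 ± 0.28, Hba-a2 -1.44 ± 0.25, Alas2 -1.05 ± 0.18 and Fth1 -1.24 ± 0.18 and the eosinophil genes Prg2 -1.55 ± 0.23 and Ear1 -1.62 ± 0.24 (adjusted p from 0.00107 to 0.0311).

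Ribosomal protein genes had a median of -1.13 after DMBA in Cyp1b1-null marrow, with 0 of 30 called, and 18 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.67e-10, 0.944 with an estimated correlation). Cy3 alone put the list of ribosomal proteins higher (camera adjusted p = 5.15e-12). Without WT oil replicate 1, 21 fell (camera adjusted p = 8.08e-19, 0.104 with an estimated correlation), with Rps14 at -1.78 ± 0.17, adjusted p = 2.67e-05 and Rpl32 at -1.70 ± 0.15, adjusted p = 1.92e-05. In all 6 genes were called with all arrays, and 1831 (820 higher, 1011 lower) without WT oil replicate 1. Omitting Cyp1b1-null oil replicate 1 gave 10 genes, and omitting DMBA replicate 2 gave 2. With slide as a random block limma called 0 (150 at an unadjusted p under 0.05), and 45 without WT oil replicate 1.

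The difference between the DMBA responses of Cyp1b1-null and WT marrow tests which of them need Cyp1b1. Few genes passed with all arrays, and Rps14 and Rpl32 were lower in log ratio without WT oil replicate 1. Cyp1a1 was well above background on neither Cyp1b1-null oil array, so no difference is given. For Spint1 it was -0.19 ± 0.78, adjusted p = 0.936, and 1.20 ± 0.50, adjusted p = 0.165 with processed signals. None is given for Ahrr and Gpnmb, dim on 1 of those arrays, and neither was called (adjusted p of 0.668 or more, 0.153 or more with processed signals). A larger or smaller AhR response without Cyp1b1 was not shown, and neither was an equal one. Cyp1b1 stood at -0.98 ± 0.31, adjusted p = 0.245 (-0.87). The p53 target Phlda3, higher after DMBA in WT, had a difference of -1.66 ± 0.32, adjusted p = 0.13. It passed without WT oil replicate 1 (-1.48 ± 0.30, adjusted p = 0.0205) and not with processed signals (-1.17 ± 0.44, adjusted p = 0.131). The differences for Ccng1 and Cdkn1a were -0.15 ± 0.25 (-0.05) and 0.95 ± 0.64 (0.25), with adjusted p of 0.543 or more. The growth factor gene Hdgf was called with all arrays, at 0.92 ± 0.13, adjusted p = 0.0415 (0.91). The fit without WT oil replicate 1 added lower differences of the ribosomal genes Rps14 -2.19 ± 0.23 and Rpl32 -1.81 ± 0.21, of Hbb-bt -2.13 ± 0.37 and Fth1 -1.56 ± 0.25 and of the macrophage gene C1qb -1.36 ± 0.23. It added higher ones of Klf1 1.03 ± 0.25, Mcm7 0.83 ± 0.21, Gfi1b 1.46 ± 0.25 and Sertad2 1.77 ± 0.41 (adjusted p from 1.47e-04 to 0.0415).

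Of the ribosomal protein genes 0 were called (median -0.68; camera adjusted p = 0.0379, 0.973 with an estimated correlation) and 0 were lower adjusted over the list alone. Omitting WT oil replicate 1, 18 were lower, 21 adjusted over the list alone (camera adjusted p = 3.92e-14, 0.114 with an estimated correlation), while Cy3 alone put the list higher (0.00949). With all arrays the erythroid and mature neutrophil lists had medians of 1.39 and 1.23 with no member called (camera adjusted p = 3.44e-07 and 5.91e-05, 0.944 for each with an estimated correlation). Without that array their medians were 0.52 and 0.09. In all limma called 2 genes (2894 at an unadjusted p under 0.05), and 744 (327 higher, 417 lower) without WT oil replicate 1. Omitting WT oil replicate 2 or 3 gave 580 or 1, omitting any WT DMBA replicate gave 0, and omitting Cyp1b1-null oil replicate 1 gave 6. Omitting Cyp1b1-null DMBA replicate 1 gave 1, and replicate 2 gave 0. With slide as a random block 0 were called (263 at an unadjusted p under 0.05), and 41 without WT oil replicate 1.

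Cyp1a1-null and WT marrow were compared after oil to ask what loss of Cyp1a1 alone changed. Trib3, Chac1, C3 and Hp rose, and members of the dendritic cell list fell. Cyp1a1 was well above background on none of the 3 Cyp1a1-null arrays and 1 of 3 WT oil arrays, so no change is given. Cyp1b1 stood at -0.33 ± 0.20, adjusted p = 0.298 (-0.43). Of the integrated stress response the pseudokinase Trib3 2.14 ± 0.41 (1.55) and Chac1 1.31 ± 0.24 (1.36) rose. So did Osgin1 1.81 ± 0.38 (1.13), superoxide dismutase Sod1 1.76 ± 0.19 (1.61) and Hspa1b 1.61 ± 0.35 (1.70). Further rises were complement C3 1.57 ± 0.36 (1.15), haptoglobin Hp 1.54 ± 0.29 (1.26), Creb3l3 1.97 ± 0.51 (1.29) and Plekhh3 1.58 ± 0.40 (0.82), and the macrophage gene C1qb 1.21 ± 0.22 (0.88). The largest falls included the eosinophil granule gene Prg3 -2.49 ± 0.65 (-1.28), the hypoxia-responsive Ankrd37 -2.31 ± 0.36 (-1.70), the interferon-induced Ifi27l2a -1.91 ± 0.45 (-1.18) and Isg15 -1.08 ± 0.23 (-0.84). Ms4a6c -1.88 ± 0.40 (-1.18), Olfm4 -1.76 ± 0.40 (-1.06) and Cd300lg -1.74 ± 0.41 (-1.05) fell too, with Rps19 -1.73 ± 0.29 (-1.50), Apaf1 -1.60 ± 0.41 (-1.03) and osteopontin (gene Spp1 -1.51 ± 0.15 (-1.50)). The plasmacytoid dendritic cell gene Siglech -1.09 ± 0.20 (-0.90) fell. Adjusted p of these genes ran from 2.52e-04 (Spp1) to 0.0456. Creb3l3 and Apaf1 lost their calls without WT oil replicate 1 (adjusted p = 0.0698 and 0.0676).

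Of 14 dendritic cell genes 2 fell, and 8 were lower and 1 higher adjusted over the list alone (camera adjusted p = 8.32e-05, 0.944 with an estimated correlation; fry adjusted p = 0.0358). The first count was 5 without WT oil replicate 1. Of 17 genes of the integrated stress response 2 rose, 3 adjusted over the list alone (camera adjusted p = 0.21), and 8 without that array (camera adjusted p = 8.19e-05, 0.114 with an estimated correlation). The ribosomal proteins went both ways. With all arrays their median was 0.49 (1.04) but the 6 called were lower, 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.727, 0.997 with an estimated correlation). Omitting WT oil replicate 1, 21 rose and 7 fell (camera adjusted p = 3.14e-10, 0.176 with an estimated correlation), while Cy3 alone put the list lower (6.35e-12). Eosinophil, basophil and mast cell genes had 3 lower, and 9 lower and 1 higher adjusted over the list alone (median -0.79 (-0.23); camera adjusted p = 5.52e-05, 0.944 with an estimated correlation), and 7 lower and 2 higher without that array (camera adjusted p = 0.0109, 0.649 with an estimated correlation). In all 875 genes were called, 256 higher and 619 lower, against 1856 (787 and 1069) without WT oil replicate 1, which shared 662. The count was 5054 without WT oil replicate 2, 3907 without replicate 3, and 512, 109 and 107 without Cyp1a1-null oil replicates 1, 2 and 3. With slide as a random block limma called 0 (1460 at an unadjusted p under 0.05), and 46 without WT oil replicate 1. All Cyp1a1-null oil arrays and no WT oil array were on slide 9 and extracted with the later version of Feature Extraction. Version as a random block left 17 genes (4 higher, 13 lower), and as a fixed term it turned the balance to 827 higher and 107 lower, with 60 of the 875 among them.

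BP was given to Cyp1a1-null mice for 12 h to ask how marrow responds without Cyp1a1. Ahrr, Spint1 and the macrophage genes Gpnmb and Msr1 rose. All 8 called genes were higher, each in 3 of 3 BP arrays above 3 of 3 oil arrays. Spint1 rose by 3.27 ± 0.50, adjusted p = 0.0218, and Ahrr, Gpnmb and Dpep2 by 2.60 ± 0.31, 2.02 ± 0.23 and 1.94 ± 0.23 (adjusted p = 0.00224 for each). The serotonin synthesis gene Tph1 rose by 1.61 ± 0.23 and Msr1 by 1.07 ± 0.16 (adjusted p = 0.0182 for each). The Fc receptor Fcgr1 rose by 1.04 ± 0.17, adjusted p = 0.0343, and the glycosyltransferase Dpy19l3 by 0.60 ± 0.10, adjusted p = 0.0473. With all arrays 0 genes fell. Cyp1a1 was well above background on no Cyp1a1-null array, so no change is given for it, and Cyp1b1 stood at 0.81 ± 0.20, adjusted p = 0.202. Ahrr log ratios were 2.42, 3.07 and 2.23 after BP and 0.16, -0.14 and -0.12 after oil. Without WT oil replicate 1, which enters only through the variance, the actin-severing AhR target Scin 1.65 ± 0.24 rose. So did the macrophage gene Adgre1 0.81 ± 0.11, Chst11 1.38 ± 0.23 and Dnah2 1.65 ± 0.25 and the p53 target Phlda3 1.18 ± 0.18 (adjusted p from 0.00253 to 0.019), and C1qtnf12 -0.86 ± 0.17 and Armc9 -0.65 ± 0.13 fell (adjusted p = 0.0482 for each).

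Of 29 monocyte and macrophage genes 1 rose, and 7 were higher and 1 lower adjusted over the list alone (median 0.29; camera adjusted p = 0.0477, 0.944 with an estimated correlation; fry adjusted p = 0.0177). The AhR battery had 1 of 17 higher, 4 adjusted over the list alone (camera adjusted p = 0.176), and 2 without WT oil replicate 1. Among p53 targets 0 were called (camera adjusted p = 0.121, fry 0.0338) and 2 were higher adjusted over the list alone. The fit without WT oil replicate 1 called 38 genes, 35 higher and 3 lower. Omitting Cyp1a1-null oil replicate 1, 2 or 3 gave 4, 3 or 3, omitting BP replicate 1 gave 3, and omitting BP replicate 3, which shared a slide with the oil arrays, gave 3634. Slide as a random block gave 5 genes and 13 without WT oil replicate 1, with slide as a fixed term 13, and within the shared slide 4, all of them higher. BP replicates 1 and 2 also differed from the oil arrays in Feature Extraction version. Version as a random block left 3 genes, and as a fixed term limma called 0 (488 at an unadjusted p under 0.05; lowest adjusted p = 0.0865). Processed signals gave 0 (2290; 0.0578), and 12 without WT oil replicate 1.

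**Figure D4:**
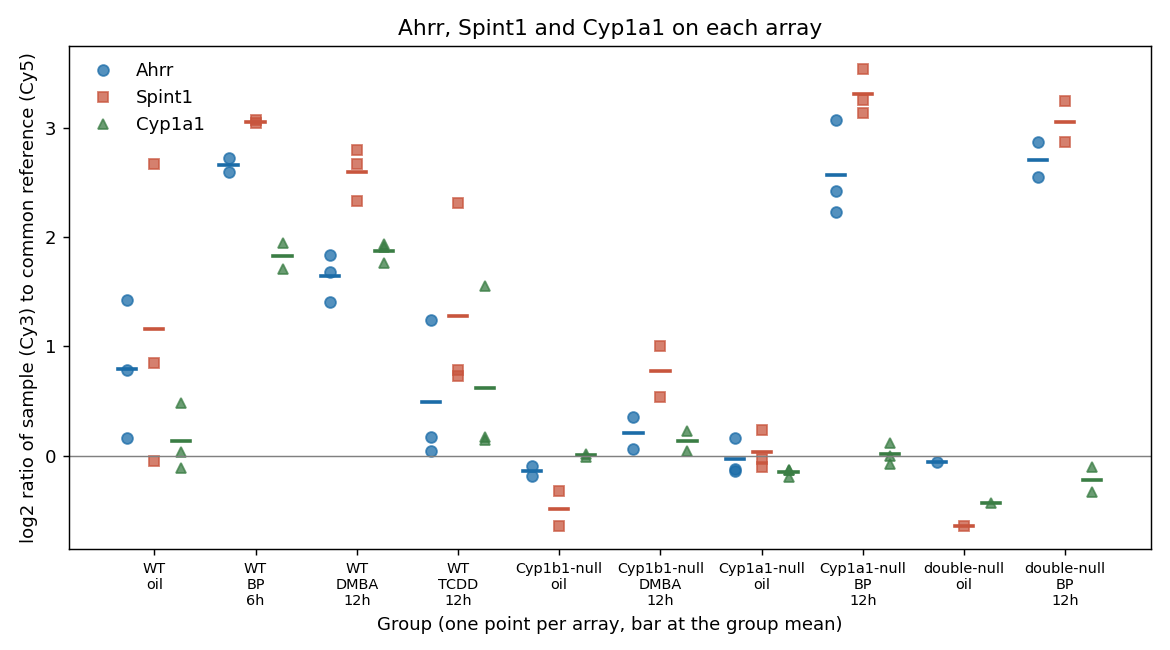
Log ratio, log2(Cy3/Cy5), of Ahrr, Spint1 and Cyp1a1 in each array (points) of the 10 groups with the group mean (bar). Ahrr lies at 2.42, 3.07 and 2.23 after BP in Cyp1a1-null and at 2.87 and 2.55 in double-null marrow, and it lies near 0 on the arrays with a high signal floor, TCDD replicates 1 and 2 and both of Cyp1b1-null DMBA.

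Double-null and WT marrow were compared after oil, with slide not told from genotype. Calls and errors assume the 1 double-null array varies like other groups. Coro1c, Lrmda and Cd74 were lower in it. Cyp1a1 was well above background on 1 of 3 WT oil arrays and not on this one, so no change is given. The Cyp1b1 probe was higher in the double-null array, by 1.41 ± 0.28, adjusted p = 0.02 (1.31), and so gave no sign of the deletion. Large rises included Trib3 2.45 ± 0.58 (1.86), Mpst 2.08 ± 0.45 (1.53) and Arl15 1.82 ± 0.30 (1.83), the scavenger receptor Cd163 1.73 ± 0.37 (1.47), the lymphocyte chemokine Xcl1 1.70 ± 0.31 (1.83) and Taf15 1.47 ± 0.28 (1.20). The quinone reductase Nqo1 0.97 ± 0.19 (0.99) rose too. Large falls included the actin-binding Coro1c -4.08 ± 0.21 (-4.07), Lrmda -2.89 ± 0.38 (-2.64), Mllt11 -2.78 ± 0.35 (-2.47) and Retnla -2.54 ± 0.46 (-2.19), the follicular homing receptor Cxcr5 -2.45 ± 0.55 (-1.78) and Ankrd37 -2.40 ± 0.51 (-1.78). Sv2a, Peg3 and Olfr745 were called too. By Cy3 signal Sv2a was at least 2.59-fold lower, with the double-null array not well above background and 2 of 3 WT oil arrays so. For Peg3, well above background on 1 of 3 WT oil arrays and not on the double-null array, no change is given. Olfr745 was at least 1.31-fold higher, with no WT oil array well above background. The B-lineage genes Cd74 -1.84 ± 0.44 (-1.41), Cd38 -1.71 ± 0.41 (-1.63), Ralgps2 -1.34 ± 0.23 (-1.24) and Pou2f2 -0.75 ± 0.16 (-0.70) fell, as did Spp1 -1.25 ± 0.21 (-1.23) and Cd68 -0.82 ± 0.17 (-0.67). Adjusted p ran from 9.36e-09 (Coro1c) to 0.049.

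Of 16 pan-B genes 2 fell, 12 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.37e-08, 0.944 with an estimated correlation). Without WT oil replicate 1, 8 fell and Pax5, again dim in WT oil, was called higher (camera adjusted p = 6.08e-07, 0.649 with an estimated correlation). Mature B genes had 3 of 15 lower, 5 adjusted over the list alone (camera adjusted p = 4.84e-07, 0.944 with an estimated correlation), and 5 without that array. Of 17 integrated stress response genes 1 rose, and 6 without that array, 9 adjusted over the list alone (camera adjusted p = 0.001, 0.176 with an estimated correlation). In all 383 genes were called, 172 higher and 211 lower, against 1491 (755 and 736) without WT oil replicate 1, with all 383 among them. Omitting WT oil replicate 2 or 3 gave 1642 or 595 genes, and the lone double-null array could not be left out. The random slide block gave 16 genes, all lower, and 82 without WT oil replicate 1.

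BP was given to double-null mice for 12 h to ask how marrow responds without either enzyme. Ahrr, Spint1 and Coro1c rose against the lone oil array, assumed to vary like the other groups. Spint1 (3.70 ± 0.74, adjusted p = 0.0473) and Ahrr (2.77 ± 0.47, adjusted p = 0.0124) rose in both BP arrays, from log ratios of -0.06 for Ahrr after oil to 2.87 and 2.55 after BP. Cyp1a1 was not well above background on any of the 3 arrays, and Cyp1b1 stood at -0.23 ± 0.29, adjusted p = 1. Coro1c, low in the lone oil array, rose by 3.82 ± 0.22, adjusted p = 4.39e-08. Crabp1 was called (adjusted p = 0.00888), at least 1.45-fold higher by Cy3 signal, with both BP arrays well above background and the oil array not so. Peg3 and Maats1, well above background on 1 of the 3 arrays, and Sv2a and Olfr519, on none, were called too, but no change is given. Large falls included the immunoglobulin segment Igkv6-14 -1.46 ± 0.26, the odorant receptor Olfr745 -1.31 ± 0.25, and Ssx2ip -0.88 ± 0.16 and Prl2b1 -0.85 ± 0.16 (adjusted p from 0.0167 to 0.0353). Slc29a4 and Syce1, well above background on 1 of 2 BP arrays, and Vmn1r80 and Invs were called too. By Cy3 signal Vmn1r80 and Invs were at least 1.21-fold and 1.2-fold lower, with neither BP array well above background. The fit without WT oil replicate 1 added rises of the AhR target Scin 2.27 ± 0.36 and the macrophage genes Msr1 0.87 ± 0.18 and Gpnmb (adjusted p from 0.00466 to 0.039), the last at least 2.79-fold higher by Cy3 signal.

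Of 17 genes of the AhR battery 1 rose, 1 adjusted over the list alone (camera adjusted p = 0.0279, 0.944 with an estimated correlation), and 3 without WT oil replicate 1 (camera adjusted p = 0.00614, 0.252 with an estimated correlation). Mature B genes had a median of 0.51 and no member called (camera adjusted p = 0.0226, 0.944 with an estimated correlation), with H2-DMb2 at 0.83 and H2-Ab1 at 0.85. In all 69 genes were called, 49 higher and 20 lower, against 127 (78 and 49) without WT oil replicate 1. Omitting BP replicate 1 gave 107. With slide as a random block 477 were called (232 higher, 245 lower), with slide as a fixed term 366, and within the slide's own arrays 21.

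The last comparison tested whether the response to BP at 12 h differed between double-null and Cyp1a1-null marrow, that is without and with Cyp1b1. Coro1c, low in the lone double-null oil array, was among those that passed. No difference was shown for Ahrr (0.16 ± 0.56), Spint1 (0.43 ± 0.89) or Cyp1b1 (-1.04 ± 0.35), with adjusted p of 0.491 or more, and Cyp1a1 was well above background on none of these arrays. With these standard errors a difference of 1 log2 unit is not ruled out for any of these genes. Those that passed included Coro1c 3.91 ± 0.26 and Shq1 1.83 ± 0.27, both higher in double-null, and Olfr745 -1.72 ± 0.30, lower (adjusted p from 3.96e-07 to 0.0261). Syce1, Peg3 and Maats1 passed too, but Syce1 was not well above background on double-null BP replicate 2, nor Peg3 and Maats1 on the double-null oil array, nor Sv2a, Olfr519 and Pvalb on any double-null array, so no change is given. The comparison rests on the single double-null oil array. Tph1 and Fcgr1, which rose after BP in Cyp1a1-null marrow, differed by -1.66 ± 0.39, adjusted p = 0.198 and -1.07 ± 0.30, adjusted p = 0.33. The megakaryocyte and platelet list had a median of -0.46, with 0 of 22 members called and 1 lower adjusted over the list alone (camera adjusted p = 0.0265, 0.944 with an estimated correlation). In all 33 genes were called, 31 higher and 2 lower, against 50 (37 and 13) without WT oil replicate 1. Omitting Cyp1a1-null BP replicate 3 gave 772, and omitting double-null BP replicate 1 or 2 gave 80 or 79. Slide as a random block gave 94, 68 without WT oil replicate 1, and 64 with slide as a fixed term.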

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

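The tests of the channels of WT oil replicate 1, of marrow composition, of a shared slide effect and of genes called after BP in both null strains, and the counts for other lone oil arrays, were chosen only after the result was seen, and the test on loss of Cyp1b1 gained its comparison with WT DMBA replicate 3 after its first value was seen.

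Lists of marrow genes stood lower in log ratio in all 6 comparisons against WT oil, with erythroid medians of -0.82 to -1.50 and G2 and M phase medians of -1.08 to -1.45, while Cy3 alone put erythroid genes higher in 5 of the 6. A marrow composition changed in every group is argued against, since without WT oil replicate 1 the erythroid median was 0 or above in 4 of 6 comparisons (-0.34 to 0.23). Non-marrow Cy3 RNA in this array as a whole is argued against by a median rank correlation of 0.926 with other arrays' Cy3 (lowest other 0.922). Liver genes at a median percentile of 96.1 in it (34.3 at most elsewhere) leave a share of other RNA open. Cy5 RNA of the marrow reference alone is argued against by liver genes at a median percentile of 99.8 (32.6 at most elsewhere). This Cy5 had a median rank correlation with others of 0.751 (lowest other 0.892). What RNA it held, and whether that lowered the lists, stays open. A composition change in single groups also stays open, as after DMBA in WT (-0.27 without that array) and in Cyp1b1-null oil (-0.34).

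In Cyp1b1-null oil 3764 genes were called, 7255 without WT oil replicate 1. For 3127 of these background correction as the cause is argued against, as they were called without it. Processed signals (share 0.78 in the same direction) are background-subtracted too, by another method than on WT oil 2 and 3, and decide nothing. A slide effect stays open: both arrays had a mean r of 0.755 with the Cyp1a1-null BP arrays of their slide (0.261 between those and the BP array of another slide). Loss of Cyp1b1 stays open too: a share of 0.756 had the same sign between the DMBA arrays of Cyp1b1-null and WT (0.806 against WT DMBA replicate 3). Between Cyp1a1-null BP arrays of the 2 slides it was 0.757. With slide as a random block and without WT oil replicate 1 the count was 1856. Slide and genotype are not told apart, as no WT array shares that slide.

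After BP in double-null marrow 49 genes were higher. A response to BP shared with Cyp1a1-null marrow as the source of the whole set is argued against, since a share of 0.469 of them was higher there. For Ahrr, Spint1 and Dpy19l3, the 3 of the 8 genes called there that were among them, it stays open, as independent calls would share 0.016. One odd double-null oil array stays open too. For 28 of the 49 genes it had the lowest log ratio of all 24 arrays while the double-null BP arrays lay within the range of the rest, and of the other 21 a share of 0.429 was higher in Cyp1a1-null. But the genes were chosen as higher than this array, and the same count for the top 49 genes of another lone oil array against 2 treated arrays ran from 1 to 38 over 25 such sets without WT oil replicate 1, so the 28 decide nothing. Coro1c stood at -3.71 in it and at 0.06 and 0.16 after BP. A BP response of double-null marrow alone stays open, since with 1 oil array it was not tested apart from that array.

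A test of the difference itself between the responses to DMBA of Cyp1b1-null and WT called 2 genes with all arrays, Hdgf (0.92) and a probe with no gene symbol. limma called 0 without background subtraction, with processed signals, the filter on 12 arrays, a block for replicate or a random one for slide, only the groups compared or the trended prior, and without any WT DMBA replicate or Cyp1b1-null DMBA replicate 2. It called 744 and 580 without WT oil replicate 1 or 2, 242 with Feature Extraction version as a fixed term, 2525 with scaled log ratios and 7835 with array weights. Camera with a preset correlation marked 11 lists (adjusted p from 3.83e-08 to 0.0379), none of them with an estimated correlation (0.944 or more). Their median differences, with those without WT oil replicate 1 in brackets, were G2 and M phase 1.43 (0.29), erythroid 1.39 (0.52), S phase 1.26 (0.29), common lymphoid and pro-B 1.24 (0.04), mature neutrophil 1.23 (0.09), pan-B 0.98 (0.20), granulocyte progenitor 0.94 (-0.14), immediate early 0.87 (0.23), mature B 0.85 (0.18), T and NK 0.47 (-0.00) and ribosomal protein -0.68 (-1.29). Cy3 alone turned the direction of all 11 lists, and scaled log ratios that of the erythroid, S phase, common lymphoid and pro-B, pan-B and mature B lists. The same kind of test for the responses to BP of double-null and Cyp1a1-null called 33 genes. Fitted differences of named genes were Coro1c 3.91, Sv2a 3.06, Peg3 2.54, Olfr519 2.26, Maats1 2.07, Shq1 1.83, Pvalb 1.74, Olfr745 -1.72 and Syce1 -1.06, but those of Sv2a, Olfr519 and Pvalb, not well above background on any double-null array, of Peg3 and Maats1, not on the oil array, and of Syce1, not on BP replicate 2, are no measured changes. Camera marked the megakaryocyte and platelet list (-0.46, camera adjusted p = 0.0265, 0.944 with an estimated correlation).

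The Cy5 signals of WT oil replicate 1, the divisor of its log ratios, held signal of liver genes above that of all other arrays. Median percentiles were 99.8 for the liver list (32.6 at most elsewhere) and 48.1 for lung (42.3), though each lung gene had a lower signal than its highest elsewhere.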

How the results depend on the processing

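Counts without WT oil replicate 1 where the oil arrays do not enter, its combinations with other settings, array weights, scaled log ratios and single slides were chosen after seeing the data. The counts of called genes are listed in the order BP 6 h in WT, DMBA in WT, TCDD in WT, Cyp1b1-null oil, DMBA in Cyp1b1-null, Cyp1a1-null oil, BP in Cyp1a1-null, double-null oil, BP in double-null, and the differences in DMBA response, between DMBA and TCDD, and in BP response. With all arrays they were 180, 0, 519, 3764, 6, 875, 8, 383, 69, 2, 158 and 33. Aquantile between arrays moves no log ratio (largest change 0), so its counts show nothing about stability. The counts were 30, 1, 1382, 3347, 33, 120, 3, 40, 23, 0, 604 and 17 without background subtraction, 3, 0, 824, 3354, 2, 55, 0, 61, 26, 0, 133 and 12 with processed signals, 177, 0, 463, 3561, 6, 955, 8, 532, 95, 2, 154 and 50 with no filter on signal, 170, 0, 573, 4044, 6, 756, 7, 169, 22, 0, 132 and 12 with a filter on 12 arrays and 195, 4, 385, 3662, 6, 1095, 6, 430, 74, 1, 81 and 35 with the mean of a gene's probes. Cy3 alone gave 73, 1, 3303, 1886, 5, 1139, 3, 97, 2, 3, 5979 and 0, and the replicate number as a block, an assumed pairing, gave 183, 2, 494, 3482, 57, 851, 9, 271, 50, 0, 132 and 33. Slide as a random block gave 0, 42, 0, 0, 0, 0, 5, 16, 477, 0, 0 and 94, and so took all calls from 7 comparisons. Slide as a fixed term, which could be fitted where a slide held both groups, gave 223 for DMBA in WT, 13 for BP in Cyp1a1-null, 366 for BP in double-null and 64 for their difference, and arrays of one slide alone gave 7247, 4 and 21 for the first 3, with lone arrays assumed to vary like the rest. Feature Extraction version gave 235, 0, 689, 4253, 20, 17, 3, 481, 77, 2, 182 and 34 as a random block and 267, 3, 874, 4749, 1282, 934, 0, 609, 76, 242, 231 and 21 as a fixed term. Fitting only the groups compared, with fewer residual degrees of freedom, gave 0, 0, 0, 0, 8426, 0, 2, 0, 21, 0, 1932 and 7, and a trended robust prior gave 117, 0, 460, 3724, 1, 863, 3, 434, 85, 0, 116 and 38. Without WT oil replicate 1 the counts were 948, 24, 1509, 7255, 1831, 1856, 38, 1491, 127, 744, 1531 and 50, with slide as a random block as well 2, 79, 0, 1856, 45, 46, 13, 82, 421, 41, 11 and 68, and with processed signals as well 68, 4, 2783, 7539, 1908, 224, 12, 314, 46, 697, 2505 and 21. Array weights, which gave WT oil replicate 1 a weight of 0.02, gave 975, 584, 2968, 9357, 9997, 2716, 8181, 3140, 193, 7835, 4888 and 2909, and log ratios scaled to one spread per array gave 96, 5, 0, 477, 4099, 5, 0, 31, 24, 2525, 779 and 18. Leave-one-out counts ran, in the same order, 6 to 1516, 0 to 842, 14 to 4342, 206 to 7255, 2 to 1831, 107 to 5054, 3 to 3634, 595 to 1642, 102 to 127, 0 to 744, 21 to 1531 and 29 to 772. That WT oil replicate 1 and slide move the counts is shown by their own settings, and for the other settings the cause was not tested.

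The share of called genes that were higher also moved. With all arrays it was, in percent, 26.1, none called, 13.7, 55.5, 16.7, 29.3, 100, 44.9, 71, 50, 81 and 93.9, against 40, 100, 20.8, 62.2, 15.2, 25.8, 100, 7.5, 100, none called, 80.5 and 100 without background subtraction, 100, none called, 28, 50.6, 100, 56.4, none called, 29.5, 100, none called, 82 and 100 with processed signals, 84.9, 0, 56.2, 43.6, 80, 59.5, 100, 63.9, 100, 66.7, 44.7 and none called with Cy3 alone and 43.8, 80, none called, 61.2, 58.7, 20, none called, 12.9, 95.8, 64.1, 67 and 100 with scaled log ratios. With Feature Extraction version as a fixed term the share in Cyp1a1-null oil was 88.5, the opposite balance. Cy3 alone shifted the median log2 change of all genes by -0.27, -0.19, -0.22, -0.25, 0.31, 0.12, -0.20, -0.14, -0.00, 0.51, -0.21 and 0.18, so that its directions are relative to these shifts.

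Of 623 values for named genes in single comparisons, 614 kept their direction and side of the threshold with no filter, 572 with a filter on 12 arrays, which left some untested, 565 with the mean of probes, 589 with replicate as a block, 579 and 569 with Feature Extraction version, 573 with the trended prior, 508 without background subtraction, 506 with processed signals, 409 with slide as a random block (211 lost their call and 3 gained one), 411 with Cy3 alone (184 and 28), 530 without WT oil replicate 1 (11 and 82), 451 with array weights (16 and 156), 376 with only the groups compared (210 and 37) and 405 with scaled log ratios (199 and 18). 1 value reversed past the threshold: Wdfy1 after DMBA in Cyp1b1-null, -1.26 ± 0.20, adjusted p = 0.0476 with all arrays, stood at 3.19 with scaled log ratios, and the cause was not tested. Of 348 tests of gene lists camera called 103 with a preset correlation, 0 with an estimated one (lowest adjusted p = 0.0915, p53 targets between DMBA and TCDD), and fry called 10. camera called, without WT oil replicate 1, 81, and 0 with an estimated correlation. Across the other settings with all lists and comparisons it called 71 to 116, and 21 of 116 and 26 of 87 with slide fixed and on single slides, where fewer comparisons were tested. The authors' per-sample values and scan day were not tried, for the reasons given above. Signal over background limits the AhR genes: Cyp1a1 was well above background in Cy3 on 10 of 24 arrays, and on 1 of the 3 in WT oil.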

Other observations

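The tests of DNA near the deleted genes were chosen only after the result was seen, and a test of the authors' table was withdrawn after its coefficients, given here as values, were seen, while the tests of AhR exposure, of the source of the Cy5 signal and of other splits were written before it.

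Several responses that an AhR ligand can bring with it showed little. NRF2 targets had at most 2 of 16 members higher (Osgin1 and Gstm1 in Cyp1b1-null oil, with Slc7a11 lower) and a camera adjusted p of 0.21 at the lowest. Glucocorticoid-responsive genes had 1 of 14 higher after BP in WT (Per1) and none called elsewhere (camera adjusted p of 0.272 or more). Of 17 circadian clock genes 1 rose after BP in WT, again Per1, with a median of 0.33 (0.02 without WT oil replicate 1; camera adjusted p = 0.0388, 0.944 with an estimated correlation), and 1 fell after TCDD in WT (Nfil3) and in Cyp1b1-null and Cyp1a1-null oil (Arntl in both). These 3 clock genes were named after their values were seen, and the sample titles give no time for the oil arrays. Heme and iron genes stood lower after DMBA than after TCDD, with 0 of 17 called and 3 lower adjusted over the list alone (median -0.35; camera adjusted p = 0.00315, 0.944 with an estimated correlation), and with 1 higher and 5 lower without WT oil replicate 1. Cy3 alone gave neither the clock nor this heme list a direction (camera adjusted p = 0.968 and 0.94). S phase and G2 and M phase genes had 7 and 5 of 29 lower in Cyp1b1-null oil, 8 and 12 adjusted over the list alone (camera adjusted p = 1.54e-05 and 1.13e-07, 0.944 for each with an estimated correlation), where the medians were -1.22 and -1.41, and -0.18 and -0.27 without WT oil replicate 1. T and NK cell genes had 3 of 26 lower (Cd2, Lck and Cd247) and Cd3e higher there (median -0.33; camera adjusted p = 0.0223, 0.944 with an estimated correlation; no direction without WT oil replicate 1, 0.897), and granulocyte progenitor genes stood at -1.64 after TCDD with none called (camera adjusted p = 0.00105, 0.944 with an estimated correlation; median -0.27, 2 lower and camera adjusted p = 0.0973 without WT oil replicate 1). Camera called stromal, bone and endothelial genes after DMBA in WT (median 0.34, none called; camera adjusted p = 0.0133, 0.944 with an estimated correlation; 0.8 without WT oil replicate 1) and against TCDD (0.29, 1 of 27 higher, Spp1; camera adjusted p = 0.0133, 0.944 with an estimated correlation). It called hematopoietic stem and progenitor, plasma cell, skeletal muscle and Y-linked and X-inactivation genes in no comparison.

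Xist had a log ratio of -3.97 in Cyp1b1-null oil replicate 2, against -0.73 to 1.24 on the other 23 arrays, and its Cy3 signal there was 6.92 on the log2 scale, with the Y-linked Eif2s3y at 5.91. Eif2s3y, singled out after its values were seen, lay at 10.51 in the Cy5 channel of WT oil replicate 1, at 6.09 in its Cy3 channel and at 5.76 to 9.13 in Cy5 elsewhere. The authors' table of 9 comparisons correlated at r of 0.416 to 0.815 with differences of group means from the files per array for the 6 against WT oil, and at 0.898 to 0.98 when WT oil replicate 1 was left out. The WT mean it implies had regression coefficients of -0.00517, 0.382 and 0.447 on WT oil replicates 1, 2 and 3.

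A first hypothesis was that the RNA labelled WT oil replicate 1 was exposed to an AhR ligand, since Cyp1a1 lay at -1.39 from the 75th percentile of its Cy3 signals (log2), against -1.61 to -1.28 on the WT BP and DMBA arrays and -4.43 and -3.97 on WT oil replicates 2 and 3. Of the 8 genes that rose after BP in Cyp1a1-null marrow, its Cy3 signal was nearer to treated WT arrays than to WT oil replicates 2 and 3 for 6 (Spint1, Ahrr, Dpy19l3, Dpep2, Tph1 and Gpnmb) and not for Fcgr1 and Msr1, where the hypothesis asked for all 8, so it stays undecided. Tph1 was lower on treated than on oil arrays in WT (-3.68 and -3.19). A second was that liver RNA alone, or a mixture of many tissues, was the source of its Cy5 signal. Of 6 tissue lists 2 lay above all other arrays in percentile, lung in rank only, where liver alone asked for 1 and a mixture for at least 4, so neither is decided. The lists of kidney, testis, brain and heart lay at 43.0, 34.0, 30.8 and 54.9, with 59.2, 64.6, 59.1 and 66.2 the highest elsewhere. Alb, Apoa1 and Ahsg had log2 Cy5 signals of 15.4, 15.1 and 15.4, against 9.15 at most elsewhere, so liver remains a candidate source. Of the 18 liver genes Tat had the highest Cy5 signal elsewhere, at 10.4. The highest lung gene, Lamp3, lay at 8.36, below its 11.8 elsewhere.

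Null alleles made in cells of another strain can keep DNA of that strain beside the deleted gene. In Cyp1a1-null oil, without WT oil replicate 1, 34 of 219 genes within 10 Mb of Cyp1a1 were called (15.5%, against 7.51% of all genes; odds ratio 2.29, Fisher's exact p = 4.74e-05, adjusted over 4 tests 1.90e-04), which flanking DNA of another strain near Cyp1a1 may explain, although neighbouring genes are not independent. Such DNA near Cyp1b1 was not shown in Cyp1b1-null oil (odds ratio 1.26, Fisher's exact p = 0.253), and in double-null oil the odds ratios were 1.42 and 1.19 near Cyp1a1 and Cyp1b1 (Fisher's exact p = 0.16 and 0.554).

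Groups of 3 against 3 allow 10 splits, too few for a share under 0.05. As many genes as in the real split were called in 1 of the 10 for TCDD in WT (519, highest other 2), 1 for Cyp1a1-null oil (875 and 2) and 1 for DMBA against TCDD (158 and 0). In these no slide held both groups, so slide is not told from group. For DMBA in WT all 10 gave as many, as the real split called 0. The split of WT oil replicate 2 and DMBA replicates 1 and 2, of one slide, from the rest called 447, which points to structure by slide. A random slide block gave 42. For BP in Cyp1a1-null 2 of the 10 gave as many, since the real split called 8 and that of BP replicates 1 and 2 of another slide, with oil replicate 1, from the rest called 593. Slide and Feature Extraction version part these BP arrays alike, and as random blocks left 5 and 3 genes.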
